A study of Mus musculus with 6 samples.

How the data were processed

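Poly(A) RNA was sequenced from mouse L-GMP cells, a progenitor-like fraction of leukaemia cells, sorted from the bone marrow of mice with acute myeloid leukaemia (AML) at 8 to 10 weeks of age, per the labels. There were 6 libraries, 3 from wild-type leukaemia and 3 from Prmt6-/- leukaemia, numbered 1 to 3 in each group by the labels. Libraries were made with an oligo(dT) mRNA kit, random-primed reverse transcription and 15 PCR cycles, per the labels' protocols. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

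The submitters' processing notes name Trim Galore, kallisto and HOMER without versions, and the build GRCm38. Per the file header, the table was written by the HOMER command for differential expression from a table of read counts, with 3 wild-type and 3 knockout columns and no option recorded. The annotation used for counting is not given in the sources used here. The expression values are on a log2 scale and were normalized between samples by the authors before they were deposited, and they run from -1.97 to 18.0. The transformation is not named in the file. Genes listed at 0 in all 6 libraries stay at 0, and genes of low level are pulled towards a common value, so differences of such genes are strongly understated. Among genes called both here and in the authors' deposited table, the median ratio of the difference here to the authors' deposited log2 fold change was 0.105 for the 325 genes with a mean under 5 and 0.881 for the 1678 genes with a mean of at least 10. The authors' deposited table also holds a log2 fold change, a p-value and an adjusted p-value per gene, from a test that the file does not name.

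The table holds 30037 rows that name a gene and 1 row that names none (0.00333% of rows), which was left out. Of the named genes, 7932 were listed at 0 in every library. In 25 rows the gene symbol had been turned into a number by a spreadsheet's date conversion. Of these genes 21 were tested and 5 were called, and none is named. Symbols were matched to GENCODE annotation of GRCm38, which placed 28151 genes (93.7%). Read depth is unknown because the deposited values are not counts, so no counting interval or detection floor is given. No pair of libraries shared identical values among genes above 0.

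Genotypes were compared with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) on the deposited log2 values as they stand. The design written before the data were examined foresaw a pseudocount of 1 on linear values. It was not applied, because the values were already on a log2 scale and some lay below 0. Genes with a value of at least 1 in at least 3 libraries were tested. A difference is knockout minus wild type on the deposited log2 scale, its error is limma's standard error, and groups are given as mean ± SD with n = 3. Single genes of the series title were also tested by an exact two-sided permutation of the group labels, whose smallest possible p with 3 against 3 is 0.1.

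Before the data were examined, 33 gene lists were written, of which 32 were tested and 1, the sex-linked genes, served only as a check. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. With an estimated correlation camera rests on the few residual degrees of freedom of 6 libraries. A call lost there is therefore weak evidence against a list. The preset test in turn gives p-values that are too small for a list whose genes are correlated above 0.01. A further 18 gene families were defined by symbol after the data had been seen. Genes to be named were fixed by a rule: the 3 genes of the series title, the 12 largest differences in each direction among called genes whose groups did not overlap and whose mean was at or above the median of tested genes (without predicted genes, Rik clones and -ps symbols), and up to 4 members with the smallest p of each list. Other members of lists or families that are named were chosen after their values were seen. Some genes that the rule or these lists would name are not reported here. Called genes near Prmt6 were counted with Fisher's exact test within 20 Mb on GRCm38.

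On simulated data with the 15454 tested genes and the spread of this comparison, planted log2 changes of 0.25, 0.5, 1 and 2 were recovered for 46%, 82%, 98% and 100% of 50 genes each. The changes were planted on the deposited scale. For low genes, whose differences that scale understates, these shares therefore overstate the power to find a fold change of that size. Of 15234 unchanged genes 11 were called. A planted list was called with a camera adjusted p of 8.23e-43, and 0 of 30 unchanged lists were. The simulated genes varied independently of each other, so false calls of lists with correlated genes were not tested. In all 188 genes were called in the simulation, far fewer than the 5102 in the data. Alternatives planned beforehand were a replicate block, leaving out each library, quantile normalization, median centring, no filter and a stricter filter of 5, limma without trend, array weights, pseudocounts of 0.1 and 5 on the linear scale, a 2-fold minimum, the authors' deposited adjusted p, an estimated correlation, fry, and windows of 5 and 50 Mb. Intensity-dependent centring (cyclic loess) and cameraPR on the authors' deposited p-values were added after seeing the data. Figures were drawn with matplotlib 3.10.9.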

Results

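Gene expression was profiled in L-GMP cells sorted from wild-type and Prmt6-/- leukaemia, with 3 libraries per genotype. Prmt6 encodes a protein arginine methyltransferase, and the series title places it between the m6A reader Igf2bp2 and the lipid transporter Mfsd2a in a pathway of leukaemia stem cell maintenance. The comparison asks how the transcriptome of this leukaemic fraction differs when Prmt6 is lost. Sequencing depth is unknown. The library medians of the deposited log2 values lay between 4.65 and 4.69. Pearson correlations across genes were 0.99953 to 0.99972 within a genotype and 0.99756 to 0.99855 between genotypes, and the first principal component, with 80.5% of the variance, separated the genotypes.

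Prmt6, the targeted gene (chromosome 3, 110246109 to 110250998, GRCm38, protein-coding), was lower in all 3 knockout libraries. Its deposited log2 values were 7.82, 7.60 and 7.41 in the wild type and 5.42, 5.46 and 5.48 in the knockout. The means were 7.61 ± 0.20 (SD, n = 3) and 5.45 ± 0.03, a difference of -2.16 (SE 0.0977, limma adjusted p = 3.57e-06). The exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The authors' deposited table gives Prmt6 a log2 fold change of -7.66 with an adjusted p of 3.05e-27, a larger change than on the shrunken scale of the sample values.

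Mfsd2a, a transporter of lysophospholipids (chromosome 4, 122946850 to 122961188), stood at a low level in both genotypes, with 3.79 ± 0.04 in the wild type and 3.91 ± 0.08 in the knockout (SD, n = 3). All 3 knockout values lay above all 3 wild-type values, yet the difference of 0.13 (95% interval 0.018 to 0.234) did not pass the limma test after adjustment (adjusted p = 0.0738, exact permutation p = 0.1), and the difference was 0.078 without knockout library 1. The authors' deposited table lists Mfsd2a with a log2 fold change of 1.40 and an adjusted p of 0.103. The interval above holds for the deposited scale, which strongly understates differences of low genes. It therefore does not exclude a larger change of the transcript. Igf2bp2, an m6A-binding protein (chromosome 16, 22059009 to 22163299), averaged 5.64 ± 0.09 in the wild type and 5.77 ± 0.15 in the knockout. Its difference of 0.13 did not pass either (limma adjusted p = 0.293, exact permutation p = 0.3), and the 95% interval of -0.065 to 0.319 includes 0; the difference was 0.077 without wild-type library 2, 0.084 without knockout library 2 and 0.21 without knockout library 3. The Igf2bp2 entry of the authors' deposited table is a log2 fold change of 0.48 with an adjusted p of 0.378.

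**Figure D1:**
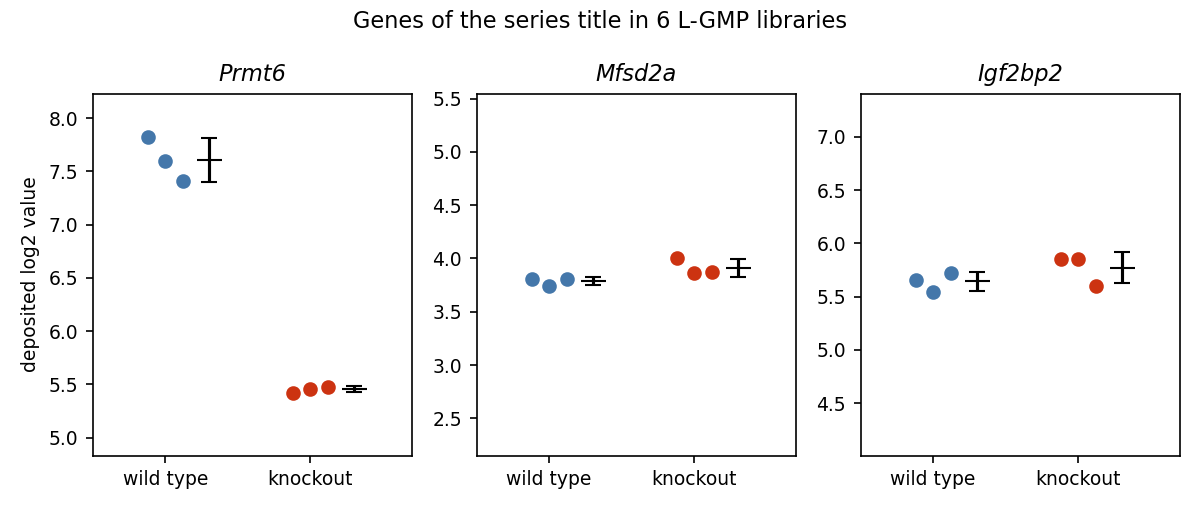
Deposited log2 values of Prmt6, Mfsd2a and Igf2bp2 in each library (points; blue wild type, red knockout), with the group mean and SD beside them (n = 3 each); each panel spans the same log2 range. Prmt6 fell from 7.61 to 5.45, while the means of Mfsd2a and Igf2bp2 each differed by 0.13. The deposited scale understates differences of low genes such as Mfsd2a, so the panels cannot be compared as fold changes.

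Of 15454 genes tested, 5102 (33.0%) passed the limma threshold, 2324 higher and 2778 lower in the knockout; after quantile normalization the majority turned, with 2827 higher and 2378 lower. The groups did not overlap for 7318 tested genes (47.4%, against 10% by chance). Of the called genes 302 differed by at least 2-fold on the deposited scale, 77 of them higher and 225 lower. The authors' deposited table holds 4798 genes past the same adjusted p, 2100 higher and 2698 lower. The calls shared by both numbered 4644, all with the same sign. Calls were mostly lower among abundant genes: in the most abundant of 8 bins of genes by level, 655 were lower and 294 higher. The 10 most abundant genes took 5.32% to 5.61% of the linear sum in wild-type libraries and 7.17% to 7.59% in knockout libraries.

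The largest increase among the genes named by rule was that of Cyp2a5, a cytochrome P450 (chromosome 7, 26835305 to 26843548), which rose from 8.08 ± 0.35 to 13.4 ± 0.24 (SD, n = 3; difference 5.33, SE 0.171, limma adjusted p = 6.55e-07). Rps4l rose by 2.81. It is annotated as a transcribed processed pseudogene, and reads shared with Rps4x could enter its value, as could those of close relatives for Cyp2a5. The retinol carrier Rbp4 rose by 2.61, the myosin Myo1e by 2.50, the granule lectin Fcnb by 2.23, the organic cation transporter Slc22a3 by 2.12, Fam110c by 2.04 and the transcriptional regulator Tsc22d1 by 2.03. The transcription factor Ets1 rose by 2.01, transferrin (Trf) by 1.92, Chil3 by 1.89 and the protease inhibitor Serpine2 by 1.59. Chil3, a chitinase-like protein with close paralogs (chromosome 3, 106147554 to 106167564), lies within 20 Mb of Prmt6. The adjusted p of these 12 genes lay between 5.20e-07 and 0.00107.

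The deepest decrease among the genes named by rule was that of Ikzf2, a zinc finger transcription factor of the Ikaros family (chromosome 1, 69531214 to 69687245), from 11.46 ± 0.03 to 7.42 ± 1.54 (SD, n = 3; difference -4.04, SE 0.596, limma adjusted p = 0.000983). Its knockout values were 6.58, 6.49 and 9.19, so that the third library lay apart while still below every wild-type value. Without knockout library 2 Siglece fell by more, at -3.67 against -3.57 for Ikzf2. With all libraries the inhibitory receptor Siglece fell by 3.66, the ephrin receptor Epha7 by 3.07, the TNF-family cytokine Ltb by 3.04 and the complement factor Cfb by 2.83. Bcl2a1b, an anti-apoptotic BCL2 relative, fell by 2.87, and its near-identical copies Bcl2a1a and Bcl2a1d fell by 2.20 and 2.12, so that the share of each is uncertain. The hexose transporter Slc2a6 fell by 2.72, the adhesion molecule Icam1 by 2.41, the lysophospholipid acyltransferase Lpcat2 by 2.39, the surface glycoprotein Cd52 by 2.35, the Src-family kinase Fgr by 2.33 and the interleukin-1 family cytokine Il1f9 by 2.32.

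**Figure D2:**
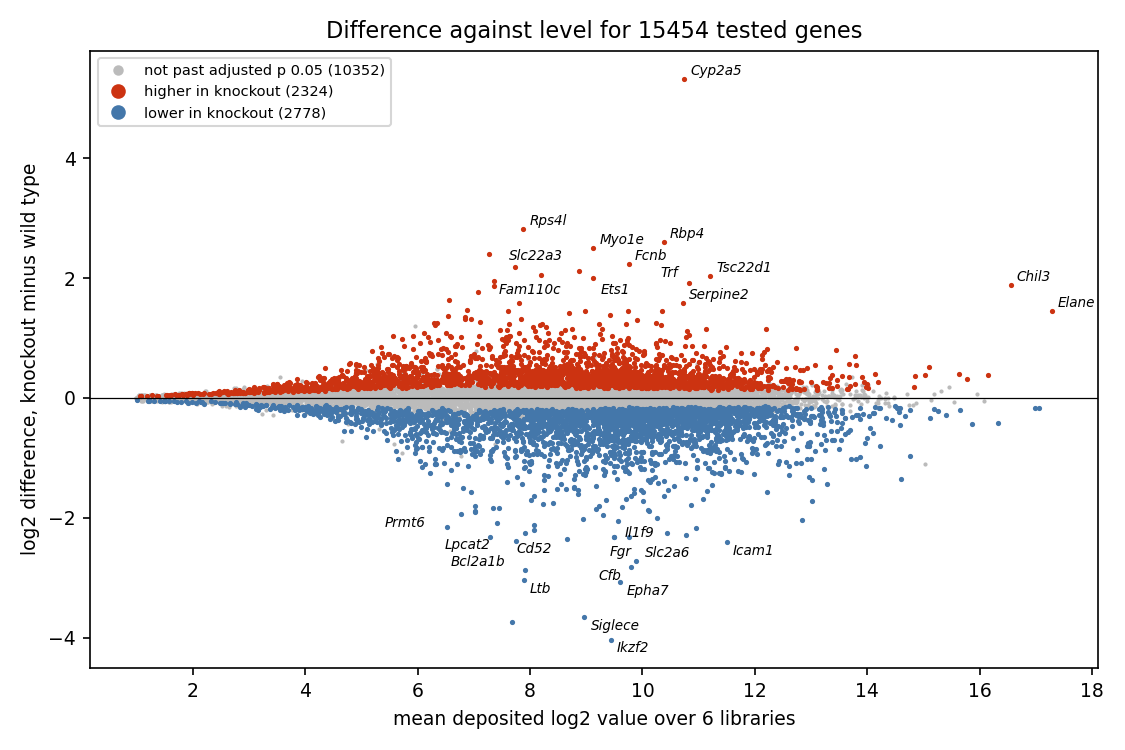
Difference between knockout and wild type (y, log2) against the mean deposited log2 value over 6 libraries (x) for 15454 tested genes; red, 2324 genes higher, and blue, 2778 lower, in the knockout at a limma adjusted p under 0.05; grey, the rest. Cyp2a5 and Ikzf2 have the largest named differences, 5.33 and -4.04, and Chil3 and Elane rose among the most abundant genes.

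Genes of the G2 phase and mitosis were lower in the knockout. Of 23 tested members 21 fell and 0 rose, and 21 passed when adjusted over the list alone, with a median difference of -0.45. Nusap1, a spindle protein, fell by 1.53, the checkpoint kinase Bub1b by 1.18, the ubiquitin-conjugating enzyme Ube2c by 0.86 and cyclin B1 (Ccnb1) by 0.71. The members that did not pass were Aurkb, at -0.04, and Mki67, at 0.15. Aurkb stood at -0.01 without wild-type library 2, at -0.06 without knockout library 1 and at -0.02 without knockout library 3, and Mki67 at 0.068 without wild-type library 3 and at 0.072 without knockout library 1. Camera called the list (adjusted p = 3.86e-10), a call lost with an estimated correlation (adjusted p = 0.314 with an estimated correlation). Replication-dependent histone genes fell too, with 37 of 63 lower and 0 higher, 41 passing when adjusted over the list alone and a median of -0.17 (camera adjusted p = 4.20e-09; adjusted p = 0.349 with an estimated correlation). Hist1h2bc fell by 1.33 and Hist2h2aa2 by 0.86; many histone genes are near-identical copies, and most of their transcripts lack the poly(A) tail that this library selects. Genes of DNA replication and the S phase showed no such fall: 3 rose and 2 fell of 24, 5 passed when adjusted over the list alone, and the median was -0.01 (camera adjusted p = 0.985). E2f1 fell by 0.50 and the flap endonuclease Fen1 rose by 0.32.

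Type I interferon response genes were lower in the knockout, with 21 of 24 fallen and 0 risen. All of these 21 also passed when adjusted over the list alone, and the median was -0.71. The RNA sensor Ifih1 fell by 1.05, the 2'-5' oligoadenylate synthetase Oas1a by 0.91 and the antiviral GTPase Mx1 by 0.82. Camera gave this list an adjusted p of 3.86e-10 and an adjusted p = 0.393 with an estimated correlation. NF-kB and inflammatory genes fell in 13 of 19 cases and rose in 1, with 15 passing when adjusted over the list alone and a median of -0.84 (camera adjusted p = 7.48e-06; adjusted p = 0.545 with an estimated correlation). Icam1 led them, the chemokine Ccl3 fell by 1.49, the NF-kB subunit Relb by 1.41 and the inhibitor Nfkbie by 1.23. Nfkbiz, an inhibitor-like nuclear regulator, was the member that rose, by 0.53. Among monocyte and macrophage genes, measured in the same libraries, the receptor Csf1r fell by 1.83, Cd68 by 0.94 and the transcription factor Irf8 by 0.70, while the chemokine receptor Ccr2 rose by 1.07. In that list 4 rose and 7 fell of 20, and 11 passed when adjusted over the list alone (camera adjusted p = 0.490).

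**Figure D3:**
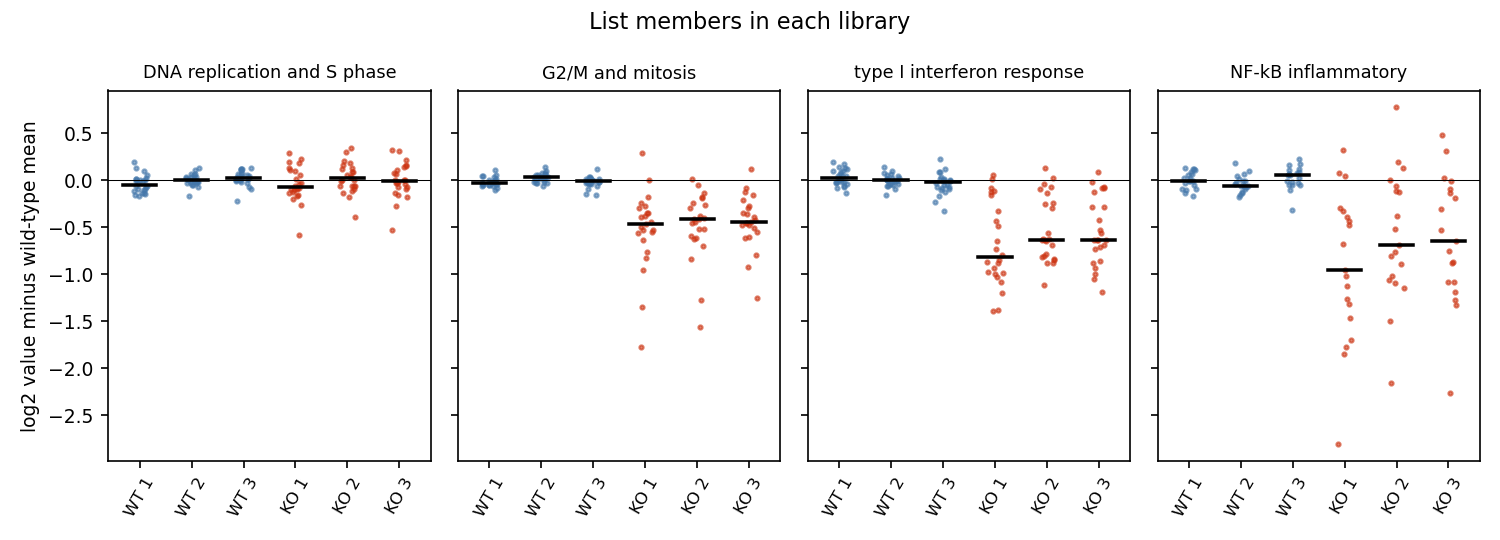
Values of list members in each library relative to the wild-type mean of the same gene (y, log2; points are genes, bars are medians) for 4 lists; blue, wild type, and red, knockout. The G2/M medians of the knockout libraries lay between -0.47 and -0.42, the interferon medians between -0.82 and -0.63 and the NF-kB medians between -0.96 and -0.64, whereas the S phase medians lay between -0.07 and 0.02.

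Apoptosis regulators were lower on balance, with 9 fallen and 1 risen of 17, 11 passing when adjusted over the list alone and a median of -0.23 (camera adjusted p = 0.000407; adjusted p = 0.314 with an estimated correlation). Those that fell included the anti-apoptotic Bcl2a1b and Mcl1 and the pro-apoptotic Casp8 (-0.49) and Bid (-0.37), while Bcl2l11, a pro-apoptotic BH3-only protein, rose by 0.72. The Mcl1 call ended without wild-type library 2 (adjusted p = 0.0719), without knockout library 1 (0.0554) or 3 (0.0623) and after quantile normalization (0.0841). Glycolysis genes fell in 11 of 20 cases and rose in 2, with 14 passing when adjusted over the list alone and a median of -0.19. Pdk1, a kinase that restrains pyruvate dehydrogenase, fell by 0.64, the phosphofructokinase Pfkp by 0.47, the lactate exporter Slc16a3 by 0.58 and Tpi1 by 0.33, or by 0.20 after quantile normalization. The glucose transporter Slc2a3 rose by 0.42, and the transporter Slc16a1 rose by 0.29 (adjusted p = 0.0483), a call that ended without any 1 of 5 libraries (adjusted p = 0.0765 without wild-type library 1, 0.114 without wild-type library 2, where the difference was 0.18, and 0.0806, 0.140 and 0.105 without knockout libraries 1, 2 and 3). It also ended with the replicate number as a block (adjusted p = 0.0522), without the low-value filter (0.0678) and in limma without trend (0.0789). The glycolysis call (camera adjusted p = 0.00128) was lost with an estimated correlation (adjusted p = 0.456 with an estimated correlation) and after intensity-dependent centring (adjusted p = 0.126, median -0.10).

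Myeloid and progenitor genes moved in both directions. Of 24 neutrophil granule and maturation genes 7 rose and 5 fell, and 13 passed when adjusted over the list alone (camera adjusted p = 0.661). Besides Fcnb and Chil3, neutrophil elastase (Elane) rose by 1.45, or by 0.81 after quantile normalization, and lipocalin 2 (Lcn2) fell by 1.09. Of 20 genes of the Hoxa/Meis1 self-renewal programme 9 rose and 2 fell, with 12 passing when adjusted over the list alone. Runx2 rose by 0.87, Meis1 by 0.49 and Hoxa11 by 0.44. Hoxa9 differed by -0.05 and did not pass; it stood at -0.08 without wild-type library 1, at -0.02 without wild-type library 3, at -0.07 without knockout library 2 and at -0.03 without knockout library 3. Camera did not call that list (adjusted p = 0.0507), and it passed in 10 of 16 alternatives, among them those without wild-type library 2 (0.0496) or 3 (0.0445) and without knockout library 1 (0.0440) or 3 (0.0240), and with the replicate number as a block (0.0380). Of 19 stem and progenitor genes 5 rose and 4 fell, with 10 passing when adjusted over the list alone (camera adjusted p = 0.964); Cd48 fell by 1.14, Lmo2 by 1.05 and Angpt1 by 0.97, and Prdm16 rose by 1.12. CDK inhibitors and p53 targets rose in 6 and fell in 3 of 22 cases, with 9 passing when adjusted over the list alone (camera adjusted p = 0.503). Phlda3 rose by 1.58, Zmat3 by 0.97, Aen by 0.59 and the CDK inhibitor Cdkn1a by 0.52, whereas the death receptor Fas fell by 1.69.

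Camera called none of the lists of lipid genes, the class to which Mfsd2a belongs, on the deposited values. Of 21 uptake and transport genes 2 rose and 5 fell, with 7 passing when adjusted over the list alone (camera adjusted p = 0.635); besides Lpcat2, the fatty acid carrier Fabp5 fell by 0.50 and the receptor Lrp1 rose by 0.80. Cholesterol synthesis genes rose in 9 and fell in 3 of 22 cases, with 13 passing when adjusted over the list alone (camera adjusted p = 0.167), led by Sc5d at 0.71 and Dhcr7 at 0.55; the list passed as higher after quantile normalization (adjusted p = 0.0373) and with cameraPR on the authors' deposited p-values (0.0326). Fatty acid synthesis and desaturation genes rose in 4 and fell in 2 of 18 cases, with 6 passing when adjusted over the list alone (camera adjusted p = 0.661), and Acsl1 rose by 0.76. Fatty acid oxidation genes rose in 2 and fell in 8 of 19 cases, with 10 passing when adjusted over the list alone (camera adjusted p = 0.0898), and the list passed as lower without the low-value filter (adjusted p = 0.0308). Etfb fell by 0.72 and Cpt1a, the carnitine palmitoyltransferase, by 0.49. Of 23 nuclear-encoded respiratory chain genes 5 rose and 6 fell, with 12 passing when adjusted over the list alone (camera adjusted p = 0.694), and Ndufs3 fell by 0.70. Of 13 mitochondrially encoded genes 3 rose and 0 fell, 3 when adjusted over the list alone (camera adjusted p = 0.374), and mt-Cytb rose by 0.38.

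Among the other arginine methyltransferases Prmt2 rose by 0.51 and Prmt3 by 0.31, so that with Prmt6 2 rose and 1 fell of 7, 3 when adjusted over the list alone (camera adjusted p = 0.985). Of 18 m6A writer, eraser and reader genes 6 rose and 2 fell, with 8 passing when adjusted over the list alone (camera adjusted p = 0.232). The reader Igf2bp1 rose by 0.52, Rbm15 by 0.44 and the writer subunit Mettl14 by 0.33, and the reader Igf2bp3 fell by 0.52. Rbm15 and Mettl14 lie on chromosome 3 within 20 Mb of Prmt6. Ribosome biogenesis and MYC target genes rose in 6 and fell in 1 of 20 cases, with 7 passing when adjusted over the list alone (camera adjusted p = 0.167); Rrp12 rose by 0.40 and Dkc1 fell by 0.41. That list passed as higher after quantile normalization (adjusted p = 0.00488) and intensity-dependent centring (0.0114). Of 78 ribosomal protein genes 16 rose and 5 fell, with 18 passing when adjusted over the list alone (camera adjusted p = 0.174), and Rpl12 rose by 0.62. Camera called the ribosomal protein list as higher after quantile normalization (adjusted p = 1.25e-05), after intensity-dependent centring (0.000351) and without knockout library 3 (0.0187). Of 20 ATF4 and unfolded protein response genes 8 rose and 3 fell, with 12 passing when adjusted over the list alone (camera adjusted p = 0.0889), and Ddit3 rose by 0.72 and Xbp1 by 0.41. The ATF4 list passed in 5 of 16 alternatives, among them that without wild-type library 3 (adjusted p = 0.0366). Of 15 Wnt target genes 3 rose and 2 fell, 5 when adjusted over the list alone (camera adjusted p = 0.443), and Cd44 fell by 1.36. Immediate early and dissociation stress genes rose in 4 and fell in 2 of 17 cases, with 7 passing when adjusted over the list alone (camera adjusted p = 0.719); Zfp36 fell by 0.53 and Egr1 rose by 0.47.

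Marker lists of other cell types were not called. Some members lay at low levels, such as Hba-a2 at 2.18 and Gp1ba at 2.13 in the wild type, and others did not, such as Cd79b at 9.56. The deposited scale understates differences of low genes, and 3.88% of the lowest of 8 bins of genes by level were called. A missing call therefore does not show that these cell types were equally frequent in both genotypes. Of 12 erythroid markers 1 rose and 1 fell, 2 when adjusted over the list alone (camera adjusted p = 0.985), and Car2 fell by 1.01. Of 7 megakaryocyte markers 1 rose, Gp1bb by 0.23, and 1 passed when adjusted over the list alone (camera adjusted p = 0.440). Of 10 B cell markers Cd79b fell by 1.15 and Ighm fell by 1.53, and 2 passed when adjusted over the list alone (camera adjusted p = 0.985). Of 10 T and NK cell markers 1 rose, Cd3d by 0.44, and 2 fell, with 4 passing when adjusted over the list alone (camera adjusted p = 0.635). Of 6 mast cell, basophil and eosinophil markers 1 rose and 2 fell, 3 when adjusted over the list alone (camera adjusted p = 0.661), and histidine decarboxylase (Hdc) fell by 1.60. Of 9 dendritic cell and MHC class II genes 4 fell, 4 when adjusted over the list alone (camera adjusted p = 0.286), and Cd74 fell by 0.57. Of 7 stromal and endothelial markers 1 fell, 1 when adjusted over the list alone (camera adjusted p = 0.927). The median, the mean and the camera direction differed in sign for the neutrophil, stem and progenitor, B cell, arginine methyltransferase, Wnt, erythroid and stromal lists.

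**Figure D4:**
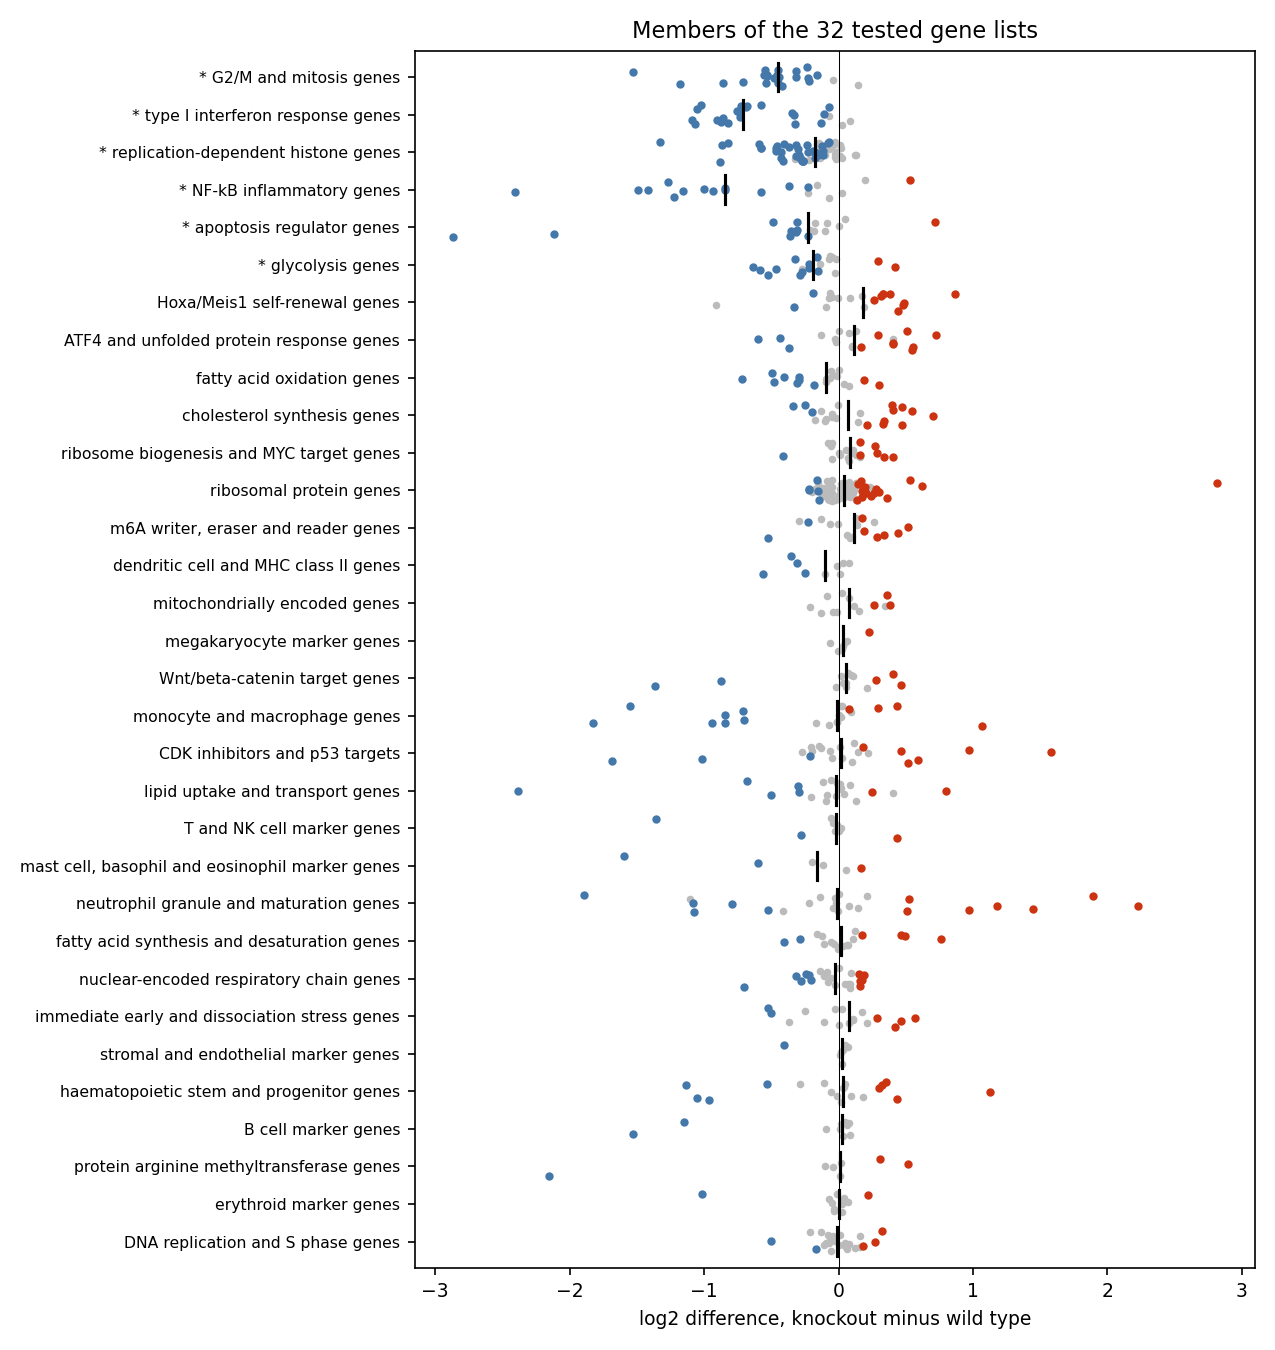
Difference between knockout and wild type (x, log2) of each member of the 32 tested lists (y), ordered by camera p; red, higher, and blue, lower, at a limma adjusted p under 0.05; grey, not past it; black bars, medians; an asterisk marks the 6 lists that camera called at the preset correlation. In the G2/M list 21 of 23 members fell and in the interferon list 21 of 24.

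Genes around the targeted locus were counted because a knockout allele can carry neighbouring variants. Within 20 Mb of Prmt6 104 of 289 tested genes were called (36.0%), against 33.0% of the genes placed elsewhere. Fisher's exact test gave an odds ratio of 1.14 (95% interval 0.886 to 1.46, p = 0.284, two-sided), so the share near the locus did not pass the test.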

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

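Intensity-dependent centring and cameraPR were chosen after the data had been seen; the other alternatives were planned. The count of 5102 genes ranged from 3888 to 4598 when 1 library was left out, which leaves fewer samples, and from 4581 to 5406 in the other fits. It was 302 with a 2-fold minimum added. Calls were 45.6% higher in the main setting and 54.3% after quantile normalization. Prmt6 kept its call in all 16 alternatives. Mfsd2a passed in none of its 15 (adjusted p 0.0551 to 0.206) and was not tested at the minimum of 5, nor Igf2bp2 in any of 16 (0.0686 to 0.593).

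Camera called 6 lists, 6 to 8 with 1 library left out and 11 after quantile normalization. CameraPR on the authors' deposited p-values called 11, fry 16 and camera with an estimated correlation 0. Why the other counts differ was not tested. With an estimated correlation the lowest adjusted p of any list was 0.314, in a test that rests on few residual degrees of freedom. The estimated correlations of the 6 called lists ran from 0.0027 (apoptosis regulators, below the preset 0.01) to 0.457 (NF-kB). A higher correlation therefore does not account for the lost call of the apoptosis list. The interferon list stood at 0.263 and the G2/M list at 0.134. If these estimates hold, the preset test gives p-values that are too small for the NF-kB, interferon and G2/M lists. Lists that passed only in alternatives were Hoxa/Meis1 (10 of 16), ATF4 (5), ribosomal proteins (3), ribosome biogenesis (2), cholesterol synthesis (1) and fatty acid oxidation (1). CameraPR added Hoxa/Meis1, neutrophil (adjusted p = 0.00204), cholesterol synthesis, ATF4 and ribosomal protein genes. Fry added Hoxa/Meis1, neutrophil, CDK inhibitor, lipid transport, cholesterol synthesis, fatty acid oxidation, m6A, ribosome biogenesis, ATF4 and megakaryocyte genes. The 6 lists kept their calls in all refits except glycolysis under intensity-dependent centring. The odds ratio near Prmt6 was 1.27 within 5 Mb and 0.976, reversed, within 50 Mb, with no window past the threshold.

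Aurkb and Hoxa9, never called, turned to 0.062 and 0.042 after quantile normalization and to 0.012 and 0.015 after intensity-dependent centring. Besides the title genes 149 genes were followed, 131 of them called. Of 2366 combinations with alternatives 2297 gave the same result, 41 lost and 14 gained a call, and 14 reversed. Calls were lost in some setting by 13 genes (Cpa3, H2-Ab1, Klf1, Mcm7, Me1, Ms4a2, Nkg7, Pecam1, Rrm2, Sdhc, Zbtb46, Znrf3 and mt-Nd1). The reversed genes lay near 0 and were never called, and the cause was not tested. With 1 library left out Ddx3y ranged from -0.012 to 0.024, Col1a1 from -0.026 to 0.081, Kdm5d from -0.023 to 0.11, Cxcl12 from -0.0081 to 0.053 and Uty from -0.0052 to 0.039. Quantile normalization gave Cxcl12 -0.0031, Uty -0.0053 and Ddx3y -0.0097, array weights gave Ddx3y -0.011, and intensity-dependent centring gave Uty -0.0013 and Ddx3y -0.0073.

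Deviations of same-numbered libraries from their group means correlated at 0.095, 0.073 and 0.17, and those of the other pairs at -0.13 to 0.052. Each library correlated best with the one of its own number. That is a hint of pairing from the data and not the design, since no label says what the numbers mark. With the replicate number as a block 5074 genes were called, 4774 of them shared, and 7 lists, with Hoxa/Meis1 added. The transcript-level and other-unit alternatives were not run, as the table is by gene and in a single unit. Unknown depth and the shrunken scale limit what low genes such as Mfsd2a can show.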

Other observations

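The gene families and every test here but the count near Prmt6 were chosen after results had been seen. Bounds on the centred values of the G2/M, interferon and NF-kB lists and of the share of lower calls were set before those centred values were known. The bounds on S phase genes, on monocyte genes and on C1qa, C1qb and C1qc were set after results had been seen. Of 18 families defined by symbol, camera called 5, each lost with an estimated correlation. MHC class I genes rose in 7 of 16 cases and fell in 0, with a median of 0.26 (adjusted p = 0.00876; adjusted p = 0.373 with an estimated correlation), while the interferon response genes fell. H2-Q10 rose by 0.67, H2-T10 by 0.53 and H2-D1 by 0.36; these genes are close copies, and their values are uncertain for that reason. The interferon regulatory factor family, matched by symbol, also took in the IRF2-binding proteins Irf2bp1, Irf2bp2 and Irf2bpl, which are not such factors. Of its 12 genes 7 fell and 1 rose (camera adjusted p = 0.0242, or 0.373 with an estimated correlation). Irf7 stood at -1.09 and Irf9 at -1.06, both also in the interferon list. The gene that rose was Irf2bpl (0.65), and Irf2bp2 (-0.27) is among the 7 that fell. V-ATPase subunit genes, which encode the proton pump of lysosomes, fell in 11 and rose in 1 of 19 cases (adjusted p = 0.00117; adjusted p = 0.373 with an estimated correlation), led by Atp6v1e1 at -0.77 and Atp6v0c at -0.70. Chemokine genes fell in 8 and rose in 2 of 25 cases (adjusted p = 0.0360; adjusted p = 0.373 with an estimated correlation), some of them shared with the NF-kB list. These 4 families kept direction and call under quantile normalization, median centring and intensity-dependent centring.

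Proteasome subunit genes fell in 13 and rose in 3 of 39 cases (adjusted p = 0.0360; adjusted p = 0.571 with an estimated correlation), but the median turned to 0.0057 under quantile normalization (adjusted p = 0.638), and the call also ended under intensity-dependent centring (adjusted p = 0.385). The chemokine receptor, integrin, C-type lectin, Siglec, Fc receptor, Src-family kinase, aminoacyl-tRNA synthetase, cathepsin, kinesin, tubulin, SOCS, Hoxb and toll-like receptor families were not called, although the C-type lectins passed as lower after quantile normalization (adjusted p = 0.0431). Single members among them moved strongly: the cytokine signalling inhibitor Socs3 rose by 1.45, the lectin Clec10a rose by 1.87 and Clec4e fell by 1.43. The Y-linked genes Ddx3y and Eif2s3y averaged 1.92 and 2.06 in the wild type and 1.92 and 2.04 in the knockout. Uty averaged 3.94 in the wild type and 3.96 in the knockout, and Kdm5d 6.60 and 6.64. All of these genes have X-linked relatives. Xist, also on that list, was not among the tested genes.

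The real grouping called 5102 genes, and the highest of the other splits called 1. With 10 splits, of which 1 reached the real count, no share under 0.05 can be had. Passenger variants beside the targeted allele are a candidate explanation for the breadth of the change. The odds ratio of calls within 20 Mb was 1.14, with an upper bound of 1.46, under the bound of 1.5 set beforehand, and 2.14 within 5 Mb. That bound was wrong for this question: of 4877 placed calls 104 lay within 20 Mb, so effects on neighbours do not make up most calls at any odds ratio, and variants acting on distant genes go with the genotype in every library. Passenger variants therefore stay open, for single neighbours such as Chil3, Rbm15, Mettl14 and Hist2h2aa2 too.

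The fall of G2/M genes is not accounted for by a level-dependent normalization error, since the list median moved from -0.45 to -0.42 after intensity-dependent centring. A smaller share of cycling cells would lower S phase genes as well. Their median of -0.013 lay above 50% of the G2/M median (-0.23) by more than the SD of the members (0.17). That bound was set after results had been seen, and the SD of the members is not the error of a median, so passing it decides nothing. In the knockout libraries the S phase medians lay between -0.07 and 0.02 and the G2/M medians between -0.47 and -0.42. For these 2 lists the values argue against a smaller share of cycling cells as the whole explanation. The fall of histone genes cannot decide this, because most of their transcripts lack the poly(A) tail that this library selects. The genotype is the factor that the design names, and how it would lower these genes was not tested.

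The fall of interferon and NF-kB genes likewise stayed after intensity-dependent centring, where the higher of the list medians was -0.72, and so it is not accounted for by a level-dependent normalization error. Macrophages among the wild-type cells would bring their abundant complement transcripts, but the highest wild-type value of C1qa, C1qb and C1qc was 2.91, far below the median level of tested genes, 7.73. This bears only on macrophages rich in these transcripts, and its bound was set after results had been seen. Because low values are pulled towards a common value, a small admixture could not be seen this way. Fewer monocytic cells in the knockout sort remain a possible explanation: of 9 monocyte genes with a mean of at least 9 in these libraries, 2 rose and 5 fell, and this cannot be told apart from lower expression per cell. The L-GMP sort would remove mature monocytes only as far as its markers, not given in the labels, exclude them.

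Of the calls in the most abundant bin of genes 69.0% were lower. A larger part of the knockout libraries taken by a few genes stays open as an explanation. The share of lower calls in the most abundant of 8 bins after intensity-dependent centring (55.8%) came out on the side of that explanation, but it decides nothing, because such centring itself moves the share towards 50%. The median difference in the third bin (0.044, against -0.059 in the top bin) does not decide it either, because it was chosen after the levels had been seen. More reads in a few genes, or a centring of the medians, would shift all bins alike and would not alone make this gap. The deposited scale, however, mutes shifts of low genes, so the gap does not exclude that explanation. A level-dependent trend between the libraries cannot be told apart from a biological fall of abundant genes: after the same centring the glycolysis median went from -0.19 to -0.10 (SD of the members 0.26 before) and its adjusted p to 0.126, and that call ended with the smaller median.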
